A study of Mus musculus with 21 samples.

How the data were processed

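RNA of whole mouse liver was hybridised to Agilent 2-colour expression arrays, 21 arrays in all, 1 per male mouse. Per the labels, each mouse was 10 weeks old, had free access to food and water and had received DEN (diethylnitrosamine, a liver carcinogen) at 12 days of age. Per the labels, RNA was taken from homogenised liver on spin columns, amplified linearly and labelled with Cy3 (the sample) against Cy5 (a pool of male and female C57BL/6 liver RNA, the reference), without a dye swap, and hybridised for 17 hours at 65 °C. The 7 groups had 3 arrays each. Replicate numbers and groups were taken from the labels, and slides, scan days and scanner models from the file headers.

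The scanner files hold, per the file headers, spot and local background brightness (intensity) for each dye, the background-subtracted and dye-normalised processed intensity, and the log10 ratio of Cy5 over Cy3 made by Feature Extraction (version 9.1.3.1 for sets a and c, version 10.7.3.1 for set b). The deposited series table holds the same log10 ratio per array, rounded to 3 significant digits: each of its columns differed from the scanner file by less than 0.005, and each column's median was 0. Deposited log10 ratios are reference over sample. All values given here are log2 of sample over reference, so their sign is opposite. The direction was checked on sex-linked genes: Xist lay below 0 on 21 of 21 arrays and Ddx3y above 0 on 21 of 21.

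Mean spot brightness was background-corrected with limma's normexp method (offset 50) and each array's log ratio was loess-normalised, with control spots at weight 0 and spots with error marks left out. Of 45018 spots, 1639 were controls. The others carried 41174 probes, of which 245 were printed on 10 spots and averaged. A probe was kept when it was well above background in Cy3 on all 3 arrays of at least 1 group, which left 26728 probes. Probes were named through their RefSeq or GenBank identifiers (26933), lists of such identifiers (96), the printed symbol (5505) or a synonym (876), and 7764 kept the array's own name. The brightest kept probe stood for each gene, which gave 18009 genes and unnamed transcripts, 15052 of them with a RefSeq symbol and 6173 with more than 1 kept probe. Probe positions are mm9 coordinates from the headers of set b and were known for 17878 of them.

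One linear model with 7 group means was fitted in limma to all 21 arrays (14 residual degrees of freedom, 4.28 prior degrees of freedom), and each comparison was a contrast of group means. The model assumes that all groups vary alike. P values were two-sided and adjusted by the Benjamini-Hochberg method over all 18009 genes within each comparison, with 0.05 as the threshold. The 4 main comparisons were little against WTa, Tfm against WTa, STAT5b knockout against WTb in C57BL/6 (B6), and STAT5b knockout against control in BALB/c. The others were little against Tfm, the difference between the 2 knockout effects, the difference between the effects of little and of the B6 knockout, the mean knockout effect over both strains, WTb against WTa, and BALB/c against B6 controls. These comparisons, 30 gene lists, the rule for naming genes and the alternatives were fixed before the data were examined.

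The 30 lists cover hormone axes (GH and IGF1), male-biased and female-biased liver genes, major urinary proteins, steroid hormone, bile acid, cholesterol, lipid, glucose and drug metabolism, proliferation, tumour and progenitor markers, p53, acute phase, interferon, clock and stress genes, zones of the lobule, and markers of 10 other cell types. They were written from general knowledge, not from these samples. Each was tested with limma's camera (preset correlation 0.01), with adjustment over 120 list tests, and again with the correlation estimated from the data. Camera compares a list with all other genes. Counts of passing members are given as adjusted over all genes and as "adjusted over the list alone".

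Named genes were, for each main comparison, the 8 largest rises and 8 largest falls among passing genes with a symbol in which every mutant array lay beyond every control array, and up to 2 rises and 2 falls per list. For tests of a difference, 4 in each direction were named, and the targeted genes and members of the GH and IGF1 list could be named everywhere. Where a gene was above background on no array of 1 group, its fold is a lower bound, taken from normalised Cy3 brightness against the dimmest probe called present on those arrays. Where it was saturated on all 3 arrays of the brighter group, the bound was taken from normalised Cy3 brightness as well. Such a bound is open to dye bias, since no dyes were swapped. For genes whose bound was above the fold of the fitted ratio, no bound is given, a choice made after the values were seen.

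The precision of each value is limited by 3 arrays per group. Median Cy3 spot brightness was 81.9 to 113 in set a, 117 to 157 in set b and 55.3 to 72.1 in set c, and 55.9% to 60.6%, 64.4% to 69.6% and 54.7% to 63.1% of probes were well above background. Saturated Cy3 probes numbered 25 to 149 per array in set a, 348 to 476 in set b and 1 to 11 in set c. The steps were tested on simulated data with 3 arrays per group. Of 100 genes changed by 2-fold 93 to 98 were found, and of 100 changed by 4-fold 99 or 100, with 7 to 18 false calls. A planted list was found with 0 false calls among 120 list tests. The simulated noise was independent between arrays, of the same spread in all groups and without saturation. These rates may thus not hold for set b, whose arrays varied and saturated more.

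Alternatives were Agilent's processed signals, median centring in place of loess, Cy3 alone with quantile normalisation, the deposited series table, no filter or a stricter filter on dim probes, the mean of a gene's probes, arrays of the compared groups only, the replicate number or the slide as a block, the 6 B6 controls together, an estimated correlation in camera, and each array left out in turn. No sample was left out. Analyses used R 4.3.3, limma 3.58.1, jsonlite 2.0.0 and data.table (1.17.8), and figures used Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6.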

Results

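Gene expression was measured in liver RNA of 21 male mice, 3 mice in each of 7 groups, each on its own 2-colour array against a common reference pooled from male and female C57BL/6 (B6) livers. Set a held B6 controls (WTa), little mice, which carry a mutation in Ghrhr, the receptor for growth hormone releasing hormone, and so lack growth hormone (GH), and Tfm mice, which lack a working androgen receptor. Set b held a second group of B6 controls (WTb) and B6 mice without STAT5b, a transcription factor that GH activates in liver. Set c held BALB/c controls and BALB/c STAT5b knockouts. The labels call the STAT5b knockouts global, so effects from outside the liver are included. All mice had been given the liver carcinogen DEN as pups. Without untreated mice, an effect of a mutation could not be told apart from a changed response to DEN. Each main comparison lay within 1 set, and differences between strains could not be told apart from differences between sets.

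Between 54.7% and 69.6% of probes were well above background on each array. Saturated Cy3 probes numbered 348 to 476 per array in set b, against 25 to 149 in set a and 1 to 11 in set c, and 242 of the 18009 genes tested were saturated on all 6 arrays of set b. A knockout effect on those genes could not be measured in B6. Across genes, the log ratios of replicate arrays correlated at 0.326 to 0.677 in Tfm, where replicate 1 lay farthest from the others, and at 0.533 to 0.926 in the other groups (genes are not independent replicates). Values are log2 of sample over reference, with a sign opposite to that of the deposited log10 ratio. Group values are means ± SD of 3 arrays and effects are differences of group means (log2 fold changes) with their SE. For every gene named as a largest rise or fall, all 3 mutant arrays lay beyond all 3 control arrays.

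The mutated genes were read first. Stat5b was lower in the knockouts of both strains on a probe on chromosome 11 (mm9, 100642099 to 100642158), at -1.77 ± 0.21 against -0.47 ± 0.19 in B6 (log2 -1.29, SE 0.169, adjusted p = 8.64e-05, a 2.45-fold fall) and at -2.43 ± 0.30 against -0.82 ± 0.27 in BALB/c (log2 -1.61, adjusted p = 8.71e-06, a 3.06-fold fall). With median centring in place of loess, the fall in BALB/c was -1.49 with an adjusted p = 0.191. A second Stat5b probe read -0.45 in B6 and -0.38 in BALB/c, and another 0.08 and 0.00, and none of these passed the test. Where the probes lie relative to the deleted part of the gene is not known. Ghrhr was not above background in WTa, little or Tfm. Ar, the androgen receptor gene, was well above background on 2 of 3 WTa arrays and on none of little (log2 -0.45, adjusted p = 0.0172) or Tfm (-0.23, adjusted p = 0.393). It was at least 1.33-fold lower in little, a call lost without WTa replicate 2 (adjusted p = 0.0522) or 3 (0.0695) or little replicate 1 (0.0601), with Cy3 alone (0.0537) and with median centring (0.207).

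**Figure D1:**
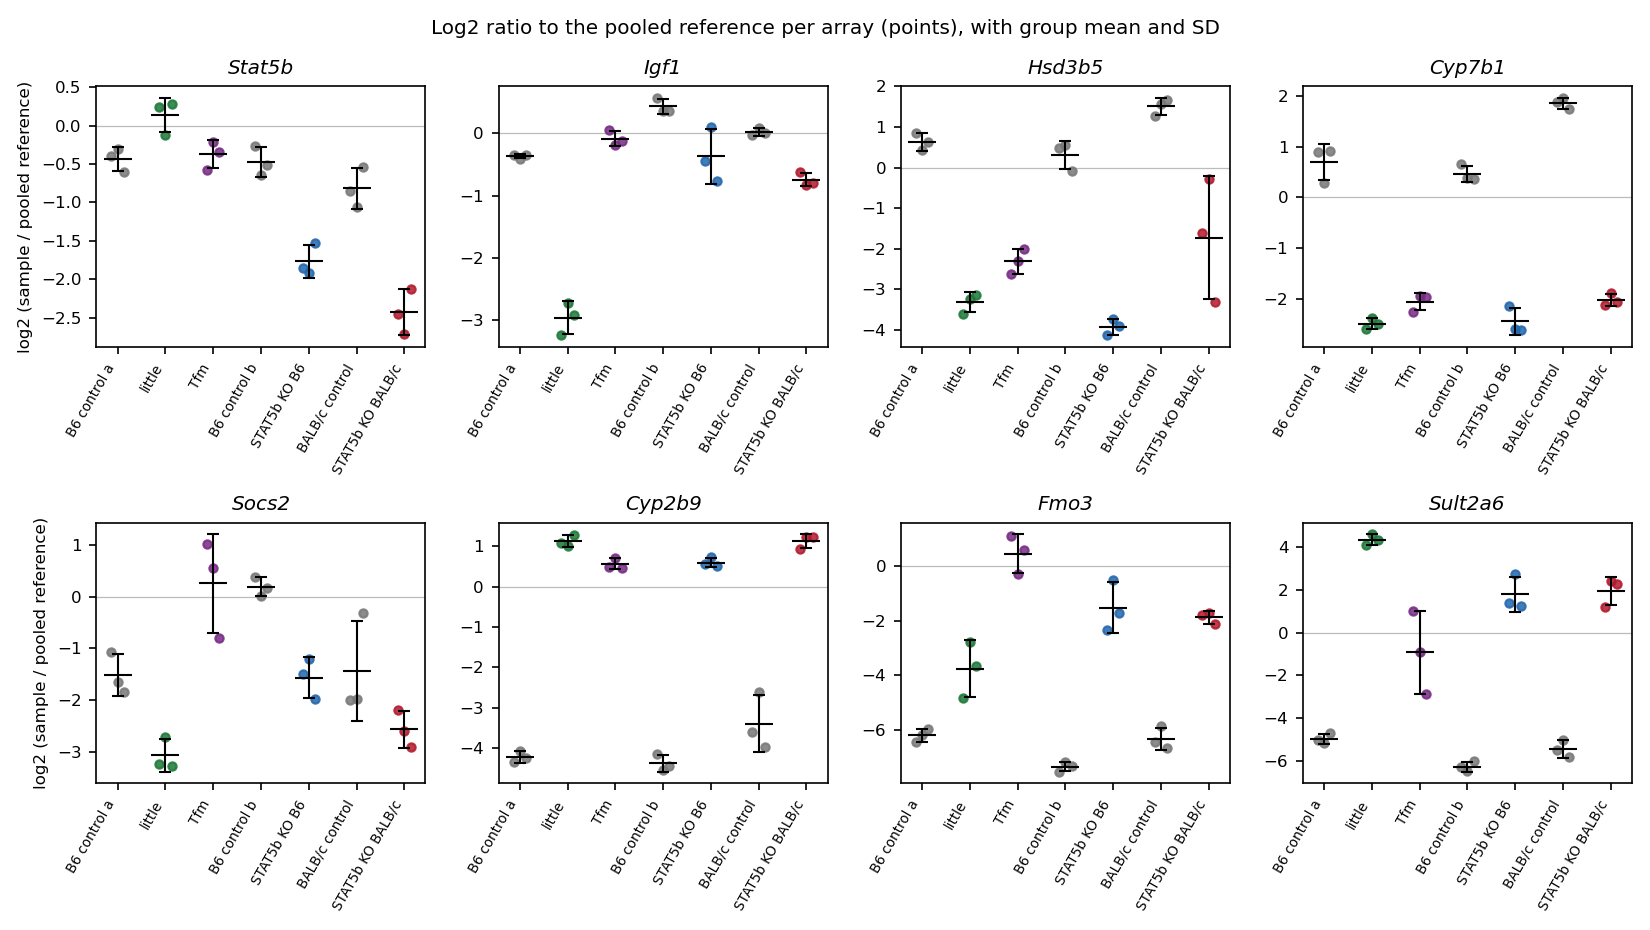
Each panel shows 1 gene (Stat5b, Igf1, Hsd3b5, Cyp7b1, Socs2, Cyp2b9, Fmo3 and Sult2a6) as the log2 ratio of sample over reference on each of the 21 arrays, in the 7 groups, with the group mean and SD. Igf1 lay at -2.96 ± 0.26 in little and -0.37 ± 0.04 in its controls, and Sult2a6 lay above its controls in all 4 mutant groups.

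The little mice show what a lack of GH changes in the DEN-treated male liver. In their livers, male-biased transcripts shifted down and female-biased transcripts up. Igf1, the circulating growth factor that GH induces, fell 6.05-fold, to -2.96 ± 0.26 from -0.37 ± 0.04 in WTa (log2 -2.60, SE 0.159, adjusted p = 2.75e-09). Sult2a6, a sulfotransferase, rose 634-fold, to 4.34 ± 0.25 from -4.97 ± 0.25 (log2 9.31, SE 0.621, adjusted p = 8.81e-09), and the fatty acid hydroxylase Cyp4a12a fell 28.0-fold, to -3.92 ± 0.48 from 0.89 ± 0.02 (log2 -4.80, SE 0.512, adjusted p = 3.8e-06). In all, 2188 genes (12.1%) changed, 1138 higher and 1050 lower, of which 169 and 230 by 2-fold or more.

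Of the 20 genes of the GH and IGF1 axis, 5 rose and 5 fell in little (5 and 5 adjusted over the list alone). Besides Igf1, falls included Egfr, the epidermal growth factor receptor (log2 -3.50, adjusted p = 3.7e-08), Igfals, which carries IGF1 in blood (-1.76, adjusted p = 0.000136), and Ghr, the GH receptor (-0.85, adjusted p = 0.000485). Igfbp1, an IGF binding protein, rose by 2.94 (adjusted p = 0.0002), and Igf1r, the IGF1 receptor, by 0.66 (adjusted p = 0.000189). Of 34 male-biased genes tested, those known to be expressed more in male than in female liver, 28 fell and none rose (31 fell adjusted over the list alone), with a median of -1.72 (camera adjusted p = 5.01e-38, and 0.000137 with an estimated correlation). Among the largest falls were Hsd3b5 (-3.95), a steroid dehydrogenase, Slco1a1 (-4.67), a transporter of organic anions, and Cyp7b1 (-3.19), an oxysterol hydroxylase. All 7 major urinary protein genes tested fell (7 adjusted over the list alone; camera adjusted p = 3.98e-10, and 0.0482 with an estimated correlation). Mup1 and Mup3 were saturated on all 3 WTa arrays, Mup4 on 2 and Mup10 on 1, so that the size of their falls could not be read in full.

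Of 34 female-biased genes, 24 rose and 2 fell in little (25 and 2 adjusted over the list alone), with a median of 1.55 (camera adjusted p = 1.99e-24, and 0.00056 with an estimated correlation). Hao2, a hydroxyacid oxidase, rose by 5.69, and Cyp2b13 and Cyp2b9, drug-metabolising enzymes, by 5.34 and 5.33. Sult2a3, Sult2a4 and Sult2a5 were not well above background on the control arrays and were higher (adjusted p = 5.8e-08, 1.46e-07 and 6.35e-11), Sult2a4 at least 47.5-fold. The 2 that fell were Lifr, a cytokine receptor (-1.88), and Cyp3a16 (-0.41), whose call was lost without WTa replicate 2 (adjusted p = 0.126) or 3 (0.105) or little replicate 2 (0.0537) or 3 (0.186). Within the 3 slides, each with 1 array of each genotype, the male-biased median was -2.02, -1.56 and -1.66 and the female-biased median 1.65, 1.44 and 1.54. Probes for Mup, Sult2a, Hsd3b, Cyp2b and Cyp4a genes may also bind close relatives within each family, and 1 of 2 probes for Hsd3b4 went the other way.

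**Figure D2:**
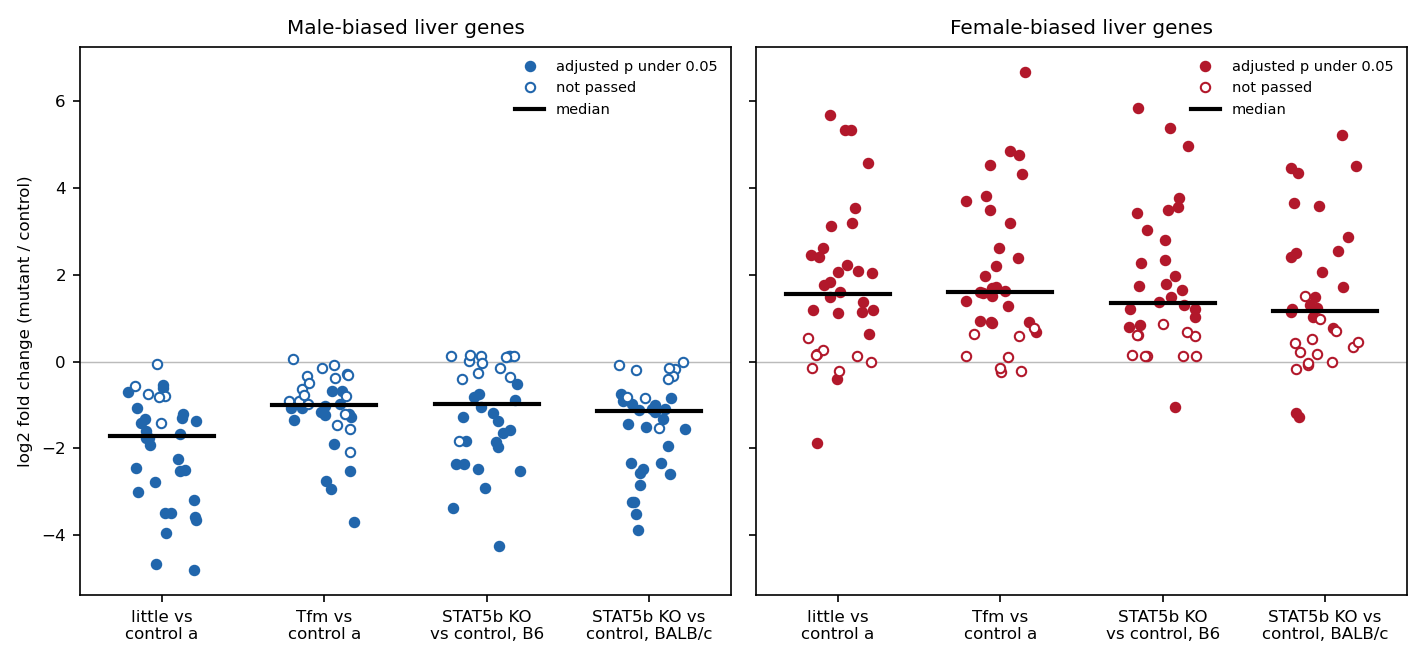
Log2 fold changes of male-biased genes (left) and female-biased genes (right) in the 4 main comparisons, with filled points for genes past the threshold, open points for the others and a line at the median. The medians were -1.72, -1.0, -0.97 and -1.13 for the male-biased genes and 1.55, 1.60, 1.34 and 1.17 for the female-biased genes.

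Metabolic genes moved in little as well, though Cyp2b10, Cyp4a10, Cd36 and Sult1e1, named below, are also on the female-biased list. Of 42 genes of drug and glutathione metabolism, 13 rose and 4 fell (16 and 7 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 0.00158, and 0.0329 with an estimated correlation). Cyp2b10 rose by 4.58, and the xenobiotic oxidase Aox3 fell by 1.56 on the log2 scale. Of 33 genes of fatty acid oxidation and PPARα targets, 9 rose (11 higher and 1 lower adjusted over the list alone), among them Cyp4a10 by 2.09 (camera adjusted p = 0.000132, and adjusted p = 0.065 with an estimated correlation). The lipogenesis list had no common direction (camera adjusted p = 0.92), with rises of Cd36, a fatty acid transporter (2.22, adjusted p = 4.18e-09), and Scd2, a desaturase (2.02), and a fall of Srebf1, a regulator of lipogenic genes (-0.78). Of 25 genes of cholesterol synthesis, 2 rose (2 adjusted over the list alone), Srebf2 by 0.90 and Dhcr24 by 0.69 (camera adjusted p = 0.00646, and adjusted p = 0.618 with an estimated correlation). That call was lost without little replicate 3 (adjusted p = 0.123). Sult1e1, the oestrogen sulfotransferase, rose by 3.54, and Ppargc1a, a coactivator of fasting genes, by 1.72.

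Of 30 liver tumour and progenitor markers, 10 rose and 2 fell in little (12 and 3 adjusted over the list alone; camera adjusted p = 0.000837, and adjusted p = 0.201 with an estimated correlation). Spink1, a trypsin inhibitor, rose by 4.10 (adjusted p = 1.26e-10), and the metallothionein Mt2, which is also an acute phase gene, by 3.51. Stress response genes shifted down, with 6 of 28 lower and 1 higher (7 and 1 adjusted over the list alone), such as the asparagine synthetase Asns at -2.26 (camera adjusted p = 0.0174, and adjusted p = 0.313 with an estimated correlation). Of 20 perivenous hepatocyte genes, 3 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0186, and adjusted p = 0.32 with an estimated correlation), and the call was lost without WTa replicate 2 (adjusted p = 0.0713) or little replicate 1 (0.0994). Interferon response genes went both ways, with 3 of 35 higher and 2 lower (4 and 2 adjusted over the list alone; camera adjusted p = 0.408), and 2 of 40 proliferation genes fell (2 adjusted over the list alone; camera adjusted p = 0.933). Of 29 acute phase genes 5 rose and 2 fell (5 and 4 adjusted over the list alone), with a median of 0.09 and a camera direction below 0 (adjusted p = 0.953). Of 23 Kupffer cell and macrophage markers, 9 rose (14 adjusted over the list alone), such as Laptm5 by 0.76 (camera adjusted p = 5.49e-08, and adjusted p = 0.193 with an estimated correlation). The call for Laptm5 was lost in at least 1 setting other than median centring. Of 22 endothelial markers, 3 rose (5 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 8.62e-05, and 0.0109 with an estimated correlation), and of 22 stellate cell markers, 6 rose (7 adjusted over the list alone), such as the proteoglycan gene Dcn by 0.75 (camera adjusted p = 0.00478, and adjusted p = 0.329 with an estimated correlation). That for Dcn, too, was a call lost in such a setting.

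The count for little was 1321 without WTa replicate 1, 1382 without WTa replicate 3, 1368 without little replicate 3 and 2578 with the slide as a block. With median centring in place of loess it was 347 (115 higher and 232 lower), and 53 of the 87 named genes that passed in little no longer did, among them Igfbp1, Ghr, Cyp4a10, Aox3, Srebf2 and Mt2 but not Igf1, Cyp4a12a, Hsd3b5 or Sult2a6. Of the 87, 22 lost their call without 1 of the arrays and 20 in at least 1 other setting.

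The Tfm mice show what the loss of androgen receptor function changes in the DEN-treated male liver. Their livers, too, gained female-biased and lost male-biased transcripts. Fmo3, a flavin monooxygenase typical of female liver, rose 102-fold, to 0.46 ± 0.71 from -6.22 ± 0.25 in WTa (log2 6.68, SE 0.453, adjusted p = 4.11e-08; probe on chromosome 1, mm9, 164884052 to 164884111). Cyp7b1 fell 6.77-fold, to -2.06 ± 0.17 from 0.70 ± 0.36 (log2 -2.76, SE 0.156, adjusted p = 2.83e-09; probe on chromosome 3, mm9, 17972286 to 17972345). In all, 447 genes (2.48%) changed, 289 higher and 158 lower, of which 83 and 42 by 2-fold or more.

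Of the 34 female-biased genes, 26 rose and none fell in Tfm (28 adjusted over the list alone), with a median of 1.60 (camera adjusted p = 1.81e-47, and 8.06e-05 with an estimated correlation). Examples were Cyp2b13 (4.86) and Cyp2b9 (4.77). Sult3a1, a sulfotransferase of the same list, was not well above background in the controls and was at least 14.5-fold higher (adjusted p = 0.000831). Of the 34 male-biased genes, 16 fell and none rose (27 adjusted over the list alone), with a median of -1.0 (camera adjusted p = 1.66e-35, and 0.000166 with an estimated correlation). Cyp4a12a fell 12.9-fold (-3.69, adjusted p = 0.000306) and Hsd3b5 7.71-fold (-2.95, adjusted p = 0.000768). Within the 3 slides, the male-biased median was -1.20, -0.58 and -1.06 and the female-biased median 1.77, 1.32 and 1.61. Of the 7 Mup genes, 1 fell (2 adjusted over the list alone; camera adjusted p = 0.000507, and adjusted p = 0.286 with an estimated correlation). That gene was Mup9 (-2.15, adjusted p = 0.0283), whose call was lost without any 1 of the 6 arrays, with adjusted p values of 0.129, 0.0544 and 0.0961 without WTa replicates 1, 2 and 3 and of 0.0546, 0.0892 and 0.0961 without Tfm replicates 1, 2 and 3. Saturation of Mup1, Mup3, Mup4 and Mup10 on WTa arrays, as given for little, limits what can be read of their falls here too.

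Igf1 was at 0.28 above WTa in Tfm and did not pass the test (adjusted p = 0.453). Of the 20 GH and IGF1 genes, 2 rose and 1 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.0208, and adjusted p = 0.193 with an estimated correlation), including Prlr, the prolactin receptor, which rose by 1.69 (adjusted p = 2.81e-05). Esr1, the oestrogen receptor, rose by 1.77 (adjusted p = 0.000206). Of 33 PPARα targets, 6 rose (8 adjusted over the list alone), among them Cyp4a14 by 2.39 and Cyp4a10 by 1.97 (camera adjusted p = 0.000204, and adjusted p = 0.0693 with an estimated correlation). Both named genes are also on the female-biased list. Drug metabolism genes went both ways, with 4 higher and 5 lower of 42 (11 and 7 adjusted over the list alone; camera adjusted p = 0.983), such as Cyp2b10 at 3.49 and Aox3 at -1.67. No gene of cholesterol synthesis passed the limma test in Tfm (none adjusted over the list alone), and the list's median of 0.32 was called by camera (adjusted p = 0.00761, and adjusted p = 0.625 with an estimated correlation), though not without Tfm replicate 3 (adjusted p = 0.181). Tumour and progenitor markers had 2 of 30 higher (4 adjusted over the list alone), with a camera adjusted p of 0.0482 that became 0.423 with an estimated correlation and 0.0515, 0.146 and 0.181 without WTa replicate 1, WTa replicate 2 and Tfm replicate 3.

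Interferon response genes were higher in Tfm, with 4 of 35 past the threshold (13 adjusted over the list alone), such as the guanylate-binding protein Gbp3 at 1.32 (camera adjusted p = 6.25e-08, and adjusted p = 0.291 with an estimated correlation). Within slides their median was 0.69, 0.01 and 0.42. No macrophage marker passed the limma test over all genes, and 6 of 23 did adjusted over the list alone (median 0.31, camera adjusted p = 1.1e-06, and adjusted p = 0.245 with an estimated correlation), with within-slide medians of 0.55, -0.05 and 0.54. No endothelial marker passed over all genes and 6 of 22 did adjusted over the list alone (median 0.31, camera adjusted p = 1.43e-07, and 0.00173 with an estimated correlation). Of 22 stellate cell markers 2 rose (5 adjusted over the list alone; camera adjusted p = 4.1e-06, and adjusted p = 0.146 with an estimated correlation). Genes of B and plasma cells, none of 17 past the threshold (none adjusted over the list alone), had a camera adjusted p of 0.0182, which became 0.455 with an estimated correlation and 0.0888 and 0.631 without WTa replicate 3 and Tfm replicate 3.

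The count for Tfm was 205 without WTa replicate 1, 211 without WTa replicate 3 and 216 without Tfm replicate 1, which correlated least with its replicates, 603 with the slide as a block and 671 against the 6 B6 controls together. More genes were higher than lower, but with Agilent's processed signals 261 were higher and 376 lower, and with Cy3 alone 533 and 636. Median centring, which moved the median of all genes from 0.02 to 0.18, left 46 higher and 7 lower and ended 24 of the 40 named calls (Fmo3, Cyp7b1, Cyp2b9 and Cyp2b13 kept their calls, Cyp4a12a, Hsd3b5, Gbp3 and Cyp4a14 lost theirs), and 15 of the 40 were lost without 1 of the arrays and 12 in at least 1 other setting.

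Little and Tfm livers, compared with each other, show how far the lack of GH and the lack of androgen signalling differ. Male-biased genes were shifted further down in little, and female-biased genes had no common direction. Sult2a6 was higher in little by 5.26 (SE 0.621, adjusted p = 3.27e-05) and Spink1 by 4.13, while Fmo3 was lower by a log2 difference of -4.23 (adjusted p = 9.52e-06) and Wfdc21 by -4.54. In all, 606 genes differed, 218 higher and 388 lower in little. Of the 34 male-biased genes, 12 were lower and none higher in little than in Tfm (17 adjusted over the list alone), with a median of -0.61 (camera adjusted p = 1.72e-14, and 0.0358 with an estimated correlation). Of the 34 female-biased genes, 6 were higher and 8 lower (9 and 10 adjusted over the list alone; camera adjusted p = 0.817). Of the 7 Mup genes 4 were lower (6 adjusted over the list alone; median -2.51, camera adjusted p = 4.64e-08, and adjusted p = 0.246 with an estimated correlation). Drug metabolism genes were higher, 9 of 42 with 1 lower (11 and 1 adjusted over the list alone; camera adjusted p = 1.9e-05, and 0.0358 with an estimated correlation). GH and IGF1 genes were lower, 6 of 20 with 2 higher (8 and 4 adjusted over the list alone; camera adjusted p = 0.00731), as were 4 of 35 interferon genes (4 adjusted over the list alone; camera adjusted p = 0.000168) and 3 of 28 stress genes (4 adjusted over the list alone; camera adjusted p = 0.000134), with adjusted p = 0.246, 0.747 and 0.279 with an estimated correlation. The count of 606 was 353 without Tfm replicate 2, 377 without Tfm replicate 1, 745 with the slide as a block, 382 with Agilent's signals and 190 with median centring (27 higher and 163 lower). With Cy3 alone the balance turned, with 316 higher and 256 lower.

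Across all genes, the effects of little and Tfm, which share the WTa controls, correlated at r = 0.701 (rho = 0.641). Simulated effects that shared only the controls correlated at r = 0.499, with a covariance of 0.0111 against 0.0799 in the data. With median centring the effects correlated at r = 0.453, for which no simulation was made. Both groups had 198 genes higher and 136 lower, against 18.3 and 9.21 for independent lists, and 4 genes changed in opposite directions. The simulations gave 0 shared genes, but they held no effects, so this could hardly differ and says nothing about the overlap. They also left out ties within slides, where residuals of arrays of different groups in set a correlated at -0.098 to 0.358.

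**Figure D3:**
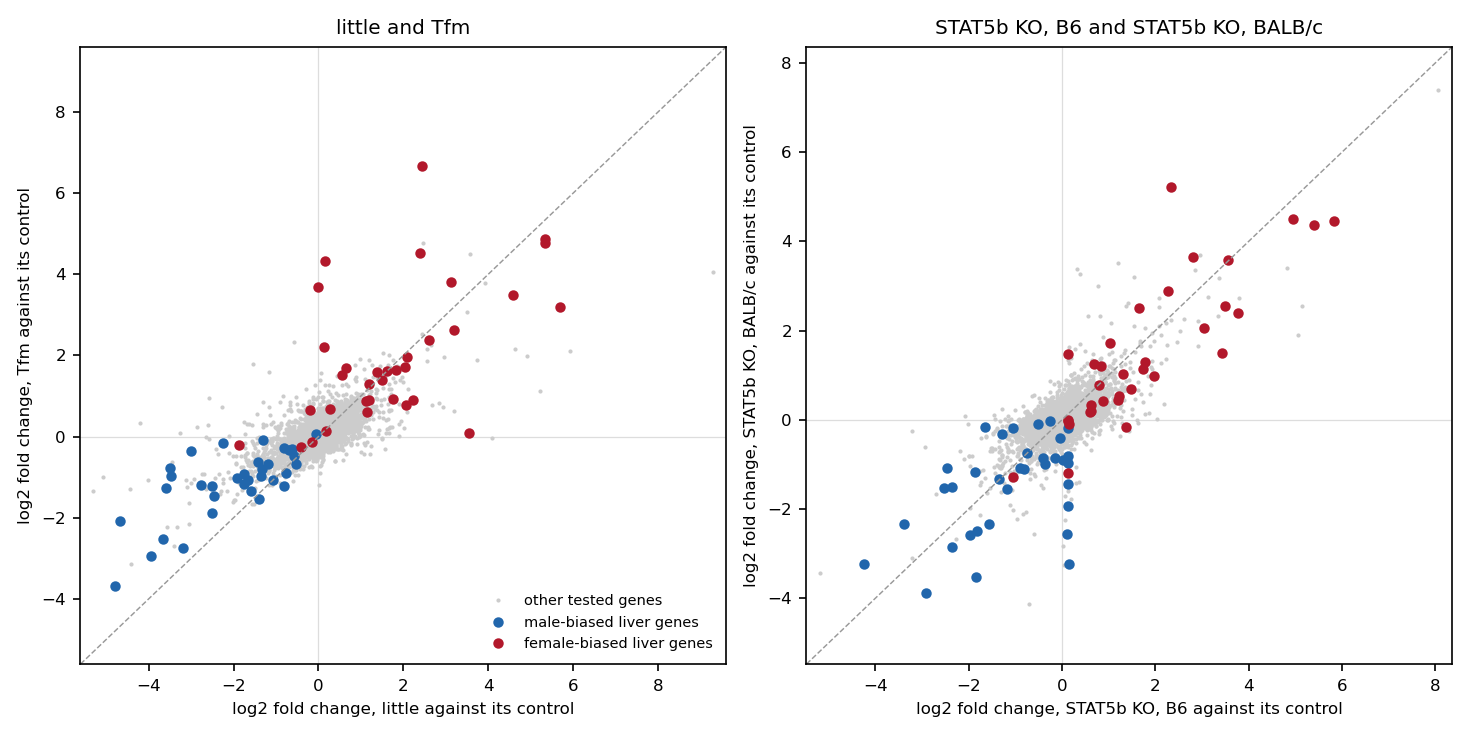
Log2 fold changes of each gene in little (x axis) and Tfm (y axis) on the left, and in the B6 (x axis) and BALB/c (y axis) STAT5b knockouts on the right, with male-biased genes in blue and female-biased genes in red. The effects correlated at r = 0.701 (left, with shared controls) and 0.675 (right), and the vertical stripe on the right is formed by genes saturated on the B6 arrays.

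The B6 STAT5b knockouts show what the global loss of STAT5b changes in a DEN-treated B6 male liver. As in little and Tfm, female-biased transcripts shifted up and male-biased transcripts down. Sult2a6 rose 266-fold, to 1.79 ± 0.83 from -6.27 ± 0.23 in WTb (log2 8.05, SE 0.621, adjusted p = 2.09e-07; probe on chromosome 7, mm9, 14811313 to 14811372), and Fmo3 57.1-fold (5.84, adjusted p = 2.14e-07). Hsd3b5 fell 18.9-fold, to -3.92 ± 0.20 from 0.32 ± 0.35 (log2 -4.24, SE 0.447, adjusted p = 7.94e-06; probe on chromosome 3, mm9, 98422848 to 98422907), and Ptk2b, a tyrosine kinase, 9.20-fold, to -1.90 ± 0.27 from 1.30 ± 0.23 (log2 -3.20, SE 0.156, adjusted p = 2.85e-10). In all, 2207 genes (12.3%) changed, 1044 higher and 1163 lower, of which 145 and 129 by 2-fold or more.

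Of the 34 male-biased genes, 20 fell and none rose in the B6 knockouts (21 adjusted over the list alone), with a median of -0.97 (camera adjusted p = 4.17e-13, and 0.00943 with an estimated correlation). The median was -1.36 over the 27 genes not saturated on all 6 arrays. Cyp7b1, saturated in the controls, was lower (adjusted p = 8.7e-10). Of the 34 female-biased genes, 24 rose and 1, Lifr, fell (28 and 1 adjusted over the list alone), with a median of 1.34 (camera adjusted p = 7.15e-28, and 0.000318 with an estimated correlation). Within the 2 slides that held both genotypes, the male-biased median was -0.93 and -0.94 and the female-biased median 1.67 and 1.06. No Mup gene passed the limma test (none adjusted over the list alone, camera adjusted p = 0.983), and 6 of the 7 were saturated on all 3 control arrays, so that their change could not be measured. The remaining 1, Mup9, was at -0.78 (adjusted p = 0.344).

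Of the 20 GH and IGF1 genes, 2 rose and 4 fell in the B6 knockouts (2 and 5 adjusted over the list alone; camera adjusted p = 0.0774). Igf1, saturated in the controls, was lower (adjusted p = 0.00325), and its call was lost with only the 6 arrays of set b (adjusted p = 0.0717). Egfr fell by 1.98 on the log2 scale, Prlr rose by 1.31 and Stat5a, the relative of Stat5b, by 0.83. The falls on this list include Stat5b, the knocked-out gene itself, and Egfr and Prlr are also on the sex-biased lists. Socs2, a feedback inhibitor that GH induces, fell (-1.75, adjusted p = 0.012), though not without knockout replicate 3 (adjusted p = 0.0542) or in at least 1 other setting. The WTb controls of this comparison read higher for Socs2 than WTa.

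Of 33 PPARα targets, 14 rose and none fell in the B6 knockouts (17 adjusted over the list alone; camera adjusted p = 5.03e-12, and 0.00238 with an estimated correlation). Cyp4a14, saturated in the knockouts, was higher (adjusted p = 0.000958), and Vnn1, a pantetheinase, rose by 1.91. Of 32 lipogenesis and lipid storage genes, 12 rose (14 adjusted over the list alone), such as Cd36 by 2.28 (camera adjusted p = 4.2e-08, and 0.0144 with an estimated correlation). Of 25 genes of cholesterol synthesis, 6 rose (10 adjusted over the list alone), such as Mvd by 1.88 and the squalene synthase Fdft1 by 1.28 (camera adjusted p = 5.2e-07, and adjusted p = 0.32 with an estimated correlation). Drug metabolism genes had 10 of 42 higher and 1 lower (14 and 2 adjusted over the list alone; camera adjusted p = 3.25e-05, and 0.00829 with an estimated correlation), such as Cyp2b10 by 3.77. Of 20 perivenous genes 6 rose (6 adjusted over the list alone; camera adjusted p = 0.00204, and adjusted p = 0.225 with an estimated correlation).

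Of 35 interferon response genes, 24 rose and none fell in the B6 knockouts (28 adjusted over the list alone), with a median of 0.84 (camera adjusted p = 1.87e-19, and adjusted p = 0.0693 with an estimated correlation). Gbp3 rose by 2.08 (adjusted p = 3.19e-05) and Igtp, an interferon-induced GTPase, by 1.91. Within the 2 slides the median was 0.69 and 0.83. Of 23 macrophage markers 11 rose as well (16 adjusted over the list alone), with a median of 0.35 (camera adjusted p = 5.5e-08, and adjusted p = 0.193 with an estimated correlation). Of 29 acute phase genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone), such as Orm3 by 3.13 (camera adjusted p = 3.6e-06, and adjusted p = 0.221 with an estimated correlation). Of 40 proliferation genes, 16 rose (21 higher and 2 lower adjusted over the list alone), such as Ccnd1, cyclin D1, by 1.27 (camera adjusted p = 1.95e-06, and adjusted p = 0.286 with an estimated correlation). Of 30 tumour and progenitor markers, 7 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.00433, 0.0605 without WTb replicate 2, and adjusted p = 0.271 with an estimated correlation), with Lcn2, a neutrophil and acute phase gene, at 2.62 and Tff3 at -1.65. Of 26 p53 and DNA damage genes 6 rose (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00761, 0.0718 without knockout replicate 3, and adjusted p = 0.201 with an estimated correlation). Markers of T and NK cells went down, with 3 of 19 lower (3 adjusted over the list alone; camera adjusted p = 0.00273, 0.0726 with the slide as a block, and adjusted p = 0.329 with an estimated correlation).

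**Figure D4:**
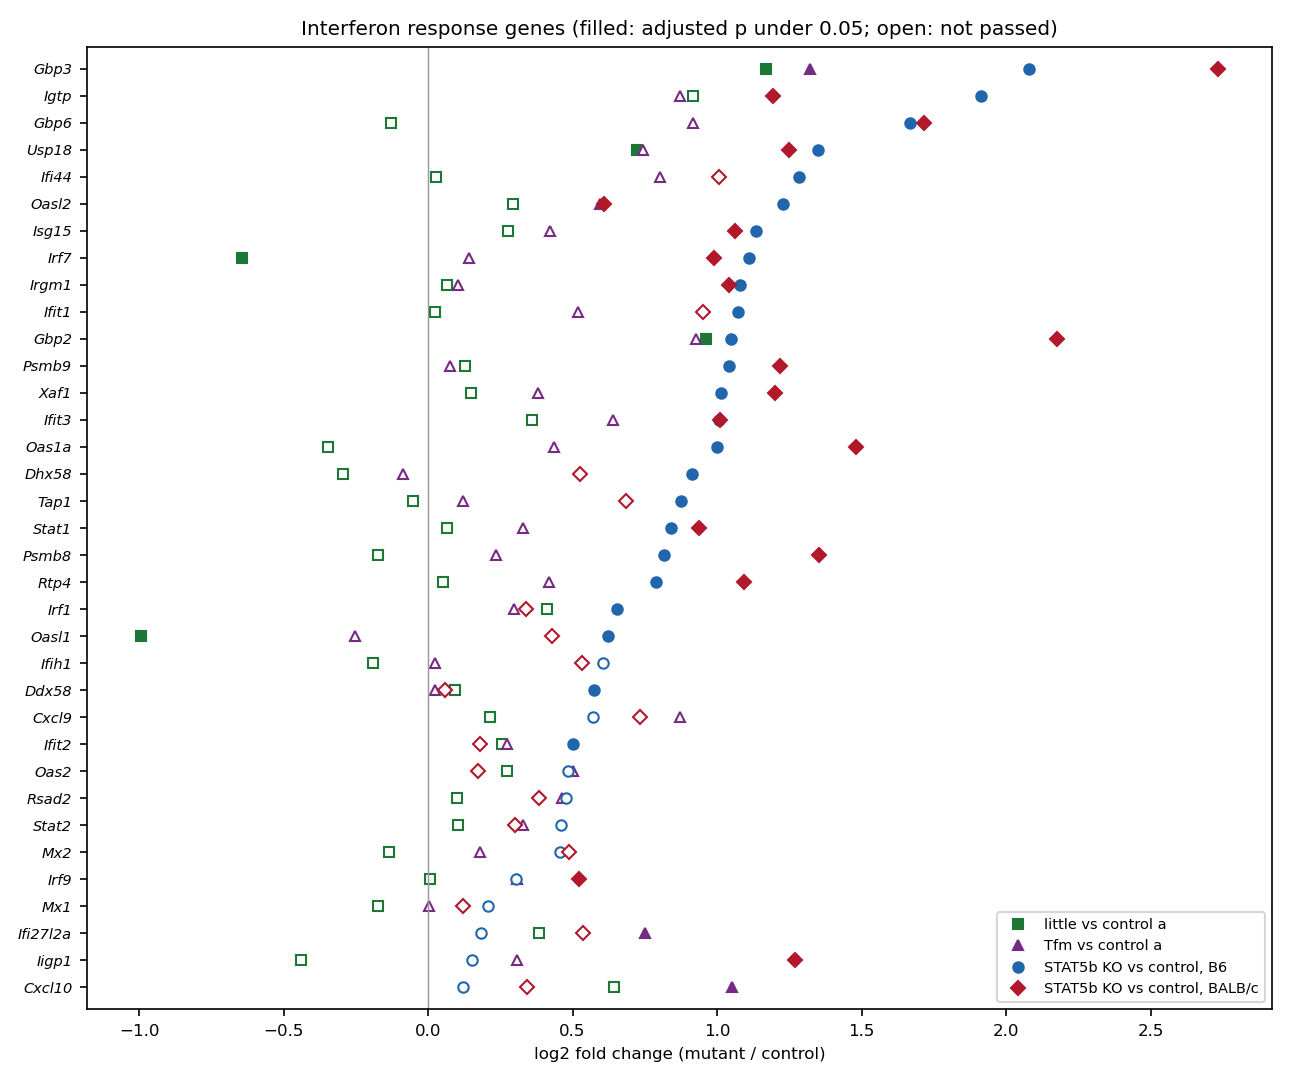
Log2 fold changes of the 35 interferon response genes in the 4 main comparisons, with filled points for genes past the threshold. The medians were 0.09 in little, 0.38 in Tfm, 0.84 in the B6 knockouts and 0.94 in the BALB/c knockouts.

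The B6 arrays varied more than those of the other sets, and with only the 6 arrays of set b 575 genes passed, against 2207 when the variance was pooled over all 21. The count was 1336 without WTb replicate 3, 1359 without knockout replicate 1, 1662 with the slide as a block and, with median centring, 447 (83 higher and 364 lower), when 36 of the 66 named genes that passed no longer did (18 without 1 of the arrays, 25 in at least 1 other setting). Median centring moved the median of all genes from -0.01 to -0.31. Against that level it ended the camera calls of the PPARα (median -0.33), drug metabolism (-0.58), macrophage (-0.12), p53 (-0.30) and perivenous (-0.34) lists, and put the medians of the lipogenesis (-0.04), acute phase (-0.44) and tumour marker lists below 0 without ending their calls.

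The BALB/c knockouts show what the global loss of STAT5b changes in the DEN-treated male liver of a second strain. Again female-biased genes shifted up and male-biased genes down. Sult2a6 rose 167-fold, to 1.95 ± 0.67 from -5.44 ± 0.41 in the BALB/c controls (log2 7.38, SE 0.621, adjusted p = 5.93e-07), and Cyp7b1 fell 14.8-fold, to -2.03 ± 0.12 from 1.85 ± 0.11 (log2 -3.88, SE 0.156, adjusted p = 2.79e-11). Cyp4a14, a fatty acid hydroxylase that is both female-biased and a PPARα target, rose 37.4-fold (5.23, adjusted p = 1.25e-07). In all, 455 genes (2.53%) changed, 268 higher and 187 lower, 183 of them by 2-fold or more.

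Of the 34 male-biased genes, 24 fell and none rose in the BALB/c knockouts (27 adjusted over the list alone), with a median of -1.13 (camera adjusted p = 5.38e-44, and 0.000116 with an estimated correlation). Hsd3b5 fell by 3.23 on the log2 scale with an SD of 1.51 among the knockouts, and its call was lost with only the 6 arrays of set c (adjusted p = 0.0666). Of the 34 female-biased genes, 19 rose and 2, Lifr and Cyp2c40, fell (21 and 2 adjusted over the list alone), with a median of 1.17 (camera adjusted p = 1.14e-35, and 0.000137 with an estimated correlation). The call for Lifr was lost in at least 1 setting other than median centring. Cyp2b9 rose by 4.5 and Fmo3 by 4.45. Within the 2 slides the male-biased median was -1.07 and -1.08 and the female-biased median 1.40 and 0.96. Of the 7 Mup genes 4 fell (7 adjusted over the list alone), with a median of -2.24 (camera adjusted p = 1.91e-11, and 0.0334 with an estimated correlation), and of -0.98 and -2.88 within the slides. Mup1 read -3.50 ± 2.40 in the knockouts and -0.26 ± 0.52 in the controls (adjusted p = 0.0146). Its call was lost without control replicate 1 (adjusted p = 0.0675) or 3 (0.0523) and in at least 1 setting with all arrays other than median centring. Mup9 lost its call in such settings too. The SEs of these effects (0.711 for Mup1 and 0.511 for Mup9) rest on a spread pooled over all groups. Among the knockouts the SD was 2.40 for Mup1 and 1.64 for Mup9.

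Of the 20 GH and IGF1 genes, 1 rose and 3 fell in the BALB/c knockouts (1 and 3 adjusted over the list alone; camera adjusted p = 0.012, and adjusted p = 0.154 with an estimated correlation). The camera call was lost without control replicate 3 (adjusted p = 0.0579) or knockout replicate 2 (0.0754) and with the slide as a block (0.125). Igf1 fell to -0.75 ± 0.11 from 0.02 ± 0.06 (-0.76, adjusted p = 0.00968), though its adjusted p was 0.0505 without control replicate 2 and 0.052 without knockout replicate 3. Egfr fell by 2.59 on the log2 scale and Prlr rose by 1.02. The 3 falls include Stat5b, the knocked-out gene itself, which also entered the camera test. Egfr and Prlr were counted in the sex-biased lists as well. Socs2 was at -1.13 (adjusted p = 0.247).

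Of 32 lipogenesis and lipid storage genes, 5 rose and none fell in the BALB/c knockouts (12 adjusted over the list alone), with Cd36 at 2.88 (camera adjusted p = 5.22e-13, and 0.00247 with an estimated correlation). Of 33 PPARα targets 7 rose (9 adjusted over the list alone; camera adjusted p = 5.26e-10, and 0.00485 with an estimated correlation), such as Cyp4a10 by 2.50, for which 1 of 4 probes went the other way. Drug metabolism genes had 6 of 42 higher and 3 lower (11 and 4 adjusted over the list alone; camera adjusted p = 0.00056, and 0.0216 with an estimated correlation), with Cyp2c38 at 3.20. In cholesterol synthesis 1 of 25 genes rose, Dhcr24 by 1.0 (1 adjusted over the list alone), a call lost in at least 1 setting besides median centring. The list had a camera adjusted p = 2.71e-06, which was 0.0529 without control replicate 2 and 0.351 with an estimated correlation.

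Of 35 interferon response genes, 18 rose and none fell in the BALB/c knockouts (25 adjusted over the list alone), with a median of 0.94 (camera adjusted p = 2.93e-34, and 0.0152 with an estimated correlation). Gbp3 rose by 2.73 (adjusted p = 1.51e-06) and Gbp2 by 2.17, and within the 2 slides the median was 0.59 and 1.03. Of 23 macrophage markers 1 rose (6 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 1.54e-05, and adjusted p = 0.291 with an estimated correlation). Of 29 acute phase genes, 8 rose and 1 fell (12 and 1 adjusted over the list alone), with the serum amyloid gene Saa2 at 3.38 (camera adjusted p = 2.77e-15, and 0.031 with an estimated correlation). Tumour and progenitor markers had 6 of 30 higher (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 8.99e-05, and adjusted p = 0.143 with an estimated correlation), with Lcn2 at 2.27. Proliferation genes had 2 of 40 higher (5 adjusted over the list alone; camera adjusted p = 4.67e-06, and adjusted p = 0.294 with an estimated correlation). Of 26 p53 and DNA damage genes 1 rose (1 adjusted over the list alone), with a camera adjusted p of 0.049 that became 0.313 with an estimated correlation and lay between 0.0529 and 0.0933 without each of the 6 arrays in turn. T and NK cell markers had 1 of 19 lower (1 adjusted over the list alone; camera adjusted p = 0.0116, 0.0574 without control replicate 3, and adjusted p = 0.423 with an estimated correlation).

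The count for BALB/c was 275 without knockout replicate 3, 487 with the slide as a block, 1016 with Agilent's processed signals, 816 with Cy3 alone and 89 with median centring. Median centring ended 26 of the 48 named calls, those of Cyp4a10 and Dhcr24 included, and kept those of Sult2a6, Cyp7b1, Cd36, Cyp2b9 and Fmo3, and 13 of the 48 were lost without 1 of the arrays and 19 in at least 1 other setting.

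The knockout effect in both strains together, and the difference between its sizes in BALB/c and B6, compare the strains. Averaged over both, Sult2a6 rose by 7.72, Fmo3 by 5.14 and Cyp2b13 by 4.88, and Cyp7b1, saturated in the B6 controls, was lower (adjusted p = 3.08e-13). In all, 2414 genes changed, 1219 higher and 1195 lower (142 and 243 with median centring). Across all genes the effects in B6 and BALB/c, which share no arrays, correlated at r = 0.675 (rho = 0.529; r = 0.469 with median centring). The strains had 185 genes higher and 111 lower in common, against 15.5 and 12.1 for independent lists, and none in opposite directions. The effect differed between strains for 33 genes, 20 higher and 13 lower in BALB/c. Ptk2b fell in B6 (-3.20) but was at -0.25 in BALB/c (difference 2.95, SE 0.221, adjusted p = 6.67e-07), with no saturated array in either strain. Of the 33 genes, 10 were saturated on all arrays of at least 1 of the 4 groups and 21 on no array. That count was 9 without B6 knockout replicate 1, 125 without B6 knockout replicate 2, 13 without BALB/c control replicate 1, 15 without BALB/c knockout replicate 3, 10 with the arrays of the compared sets only (3 higher and 7 lower) and 7 with median centring. With the slide as a block, 10 were higher and 13 lower, and with the replicate number as a block 25 and 26, so that the direction of the balance was not settled.

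Little and the B6 knockouts lie in different sets, so the difference between their effects would need both sets of B6 controls to be alike. They were not, since 3359 genes differed between them and the interferon genes were at a median of -0.28 in WTb (camera adjusted p = 0.00788, and adjusted p = 0.848 with an estimated correlation). The differences given here thus follow the sets as well as the mice. In all, 881 genes differed, 481 higher and 400 lower in little, of which 33 were saturated on all arrays of at least 1 of the 4 groups. Spink1 (3.48, adjusted p = 3.12e-06) and Krt23 (2.61, adjusted p = 0.0135) had higher effects in little, and Wfdc21 a lower one (-4.25, adjusted p = 1.68e-06). Interferon genes differed by a median of -0.78 (8 of 35 lower, 17 adjusted over the list alone; camera adjusted p = 2.34e-11), lipogenesis genes by -0.84 (4 of 32 lower and 1 higher, 10 and 1 adjusted over the list alone; camera adjusted p = 1.56e-05), acute phase genes by -0.64 (4 of 29 lower, 11 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.000134) and male-biased genes by -0.86 (9 of 34 lower, 15 lower and 1 higher adjusted over the list alone; camera adjusted p = 3.83e-09), with adjusted p = 0.597, 0.168, 0.658 and 0.12 with an estimated correlation. Of these lists, 4 lipogenesis, 7 acute phase and 7 male-biased genes were saturated on all 6 B6 arrays of set b, where no knockout effect could be read. Proliferation genes differed by -0.28 (3 of 40 lower, 5 adjusted over the list alone; camera adjusted p = 0.000134, and adjusted p = 0.714 with an estimated correlation). T and NK cell markers differed by 0.43 (4 of 19 higher, 6 adjusted over the list alone; camera adjusted p = 0.000353) and endothelial markers by 0.39 (3 of 22 higher, 8 adjusted over the list alone; camera adjusted p = 0.000537), with adjusted p = 0.641 and 0.0895 with an estimated correlation. The effects of little and the B6 knockouts correlated across genes at r = 0.489 (0.414 without WTb replicate 2; rho = 0.221), those of Tfm and the B6 knockouts at r = 0.384 (rho = 0.0603). With median centring the latter turned, to r = -0.0711. The count of 881 was 528, 407 and 433 without WTa replicates 1, 2 and 3, 549 and 530 without little replicates 2 and 3, 1833 and 390 without WTb replicates 2 and 3, 543 without knockout replicate 1, 314 with Agilent's signals (132 higher and 182 lower, a turned balance, as with the deposited series table at 134 and 184), 409 with the arrays of the compared sets only and 2 with median centring.

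Over the 4 main comparisons, 60 genes were higher in all 4 and 44 lower in all 4. No expected number was computed, and calls in little and Tfm are not independent, since both use the WTa arrays. With median centring only 46 genes were higher and 7 lower in Tfm, which limits the shared counts to these numbers at most. Of the 34 male-biased genes, 10 were lower in all 4 and 2 in none, though 7 were saturated on all 6 B6 arrays of set b and so could not be called there. Of the 34 female-biased genes, 16 were higher in all 4 and 4 in none, with 4 of the 34 saturated in the same way. Of the 35 interferon genes, Gbp3 alone was higher in all 4.

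**Figure D5:**
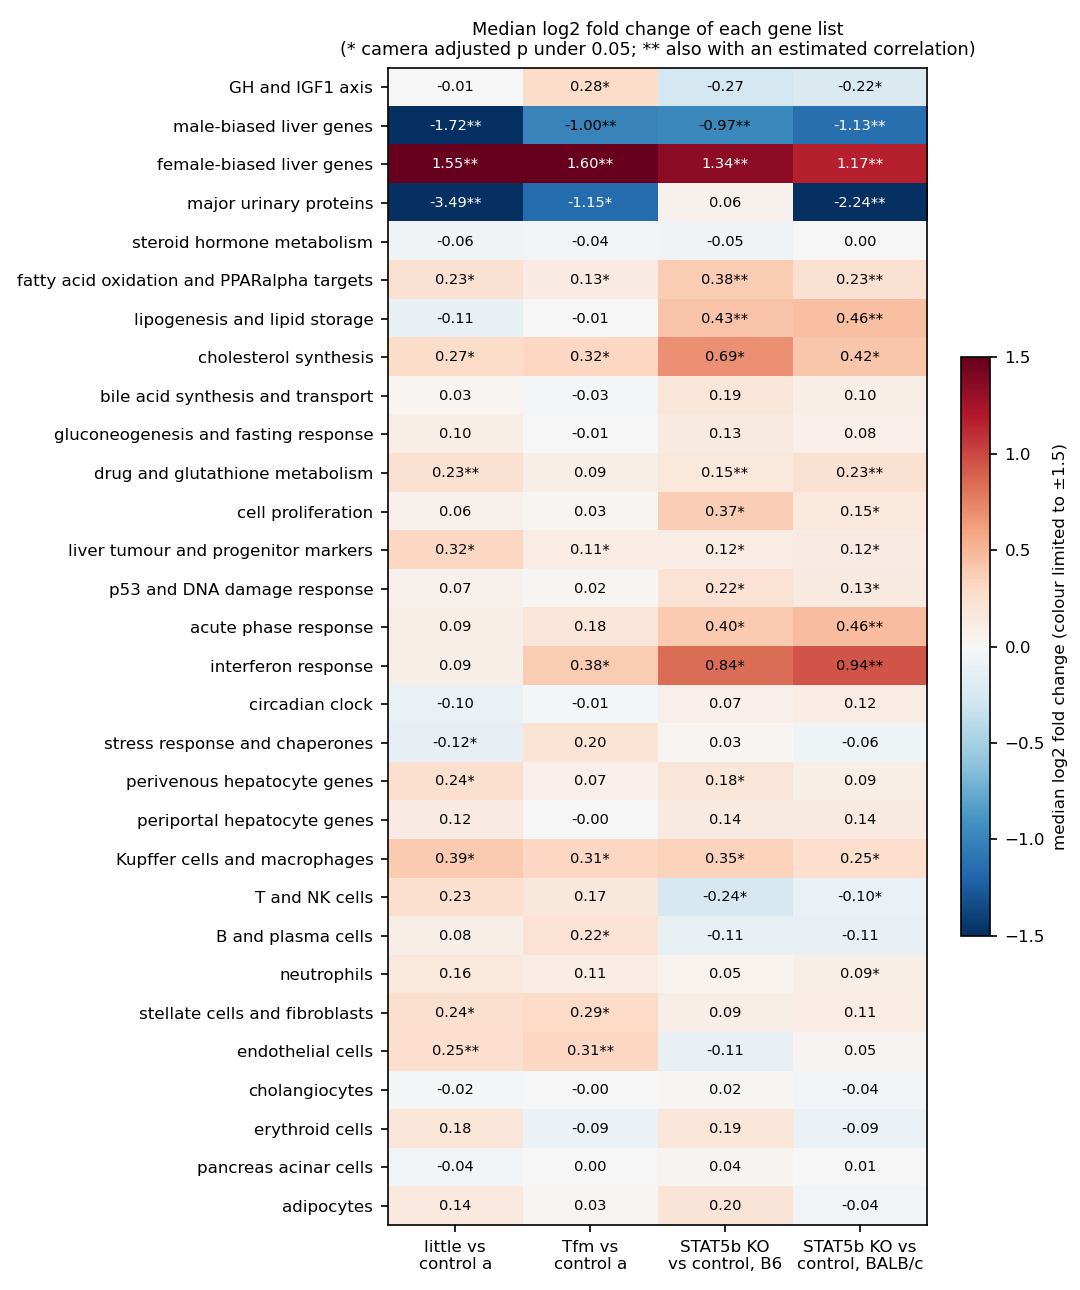
Median log2 fold change of the members of each of the 30 gene lists (rows) in the 4 main comparisons (columns), with colours limited to 1.5 in either direction. A star marks a camera adjusted p under 0.05 and 2 stars mark lists for which it also held with an estimated correlation, as for the male-biased and female-biased genes in all 4 comparisons.

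Other lists had no camera call in any of the 4 comparisons, given here as genes higher and lower in little, Tfm, B6 and BALB/c knockouts. Steroid hormone genes (25 tested) had 5 and 8, 1 and 3, 1 and 4, and 1 and 3 (7 and 8, 2 and 5, 3 and 4, and 3 and 3 adjusted over the list alone), with rises of Cyp17a1, a steroid hydroxylase, by 2.07 in little and 1.78 in the B6 knockouts. Bile acid genes (25) had 5 and 4, 0 and 1, 3 and 2, and 1 and 2 (5 and 4, 2 and 2, 5 and 2, and 3 and 2 adjusted over the list alone). Gluconeogenesis genes (20) had 3 and 1, none, 1 and 1, and none (3 and 1, none, 2 and 1, and none adjusted over the list alone). Clock genes (21) had 1 lower in little and 1 in the B6 knockouts (1 and none adjusted over the list alone), and periportal genes (17) had 2 and 1, 0 and 1, 1 and 1, and 0 and 1 (2 and 1, 1 and 1, 1 and 1, and 4 and 3 adjusted over the list alone). Among markers of other cells, cholangiocyte genes (13) had 1 and 2 in little and none elsewhere (the same numbers adjusted over the list alone), and erythroid genes (9) 1 and 1, 0 and 1, 1 and 1, and 1 and 1 (1 and 1, 0 and 1, 1 and 2, and 1 and 1 adjusted over the list alone). Pancreas acinar genes (13) had 1 higher in the B6 knockouts (1 adjusted over the list alone), and adipocyte genes (7) 1 and 1 in little and 1 higher in the B6 knockouts (1 and 2, and 1, adjusted over the list alone). Krt23, a keratin, was the cholangiocyte gene that rose in little (2.67, adjusted p = 0.000142), and Alas2, an enzyme of haem synthesis, fell in all 4 comparisons (-1.59, -1.35, -0.81 and -1.11). The BALB/c call was lost with only the 6 arrays of set c (adjusted p = 0.0866), and those in Tfm and BALB/c with median centring (0.727 and 0.817). Neutrophil genes (10 tested) had a camera call in BALB/c alone, with 1 higher (1 adjusted over the list alone; camera adjusted p = 0.0182, 0.0538 without control replicate 1, 0.0512 without knockout replicate 2, and adjusted p = 0.308 with an estimated correlation).

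Control mice were compared last. Between the B6 controls of sets a and b, which the labels give the same strain, sex, age and treatment, 3359 genes differed, 1421 higher and 1938 lower in WTb, 86 of them by 2-fold or more. Cyp2c40, a female-biased gene, was higher in WTb by 1.73 (SE 0.192, adjusted p = 0.000184), Socs2 by 1.71 (adjusted p = 0.011), and Tymp lower by a log2 difference of -1.57 (adjusted p = 0.000728). Khsrp was at -1.35 but at 0.82 with Cy3 alone (adjusted p = 0.0125). Interferon genes were lower in WTb, 6 of 35 with 1 higher (10 and 1 adjusted over the list alone; camera adjusted p = 0.00788, and adjusted p = 0.848 with an estimated correlation). The count was 1348 without WTa replicate 2, 1853 without WTa replicate 3, 1444 without WTb replicate 3, 4 with median centring and 6899 with Cy3 alone. The balance turned with Cy3 alone (3963 higher and 2936 lower), with Agilent's signals (1103 and 997), with the deposited series table (1108 and 1000) and with only the compared arrays (732 and 663). BALB/c controls differed from the 6 B6 controls in 6957 genes, 3839 higher and 3118 lower, with Crym, a thyroid hormone binding protein, higher by 2.88 (adjusted p = 8.7e-13) and Cyp4a14 lower by a log2 difference of -4.32. Cholesterol synthesis genes (10 of 25 lower and 3 higher, the same numbers adjusted over the list alone; camera adjusted p = 0.0249) and macrophage markers (11 of 23 lower and 1 higher, the same numbers adjusted over the list alone; camera adjusted p = 0.000565) were lower in BALB/c, with adjusted p = 0.921 and 0.729 with an estimated correlation. With median centring 4054 genes were higher and 250 lower. Both comparisons follow the sets as well as the mice.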

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

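The tests of macrophage number, of another GH route, of the strain difference of the Mup genes and of their spread between arrays were chosen after the result they address was seen.

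The knockout effect differed between BALB/c and B6 for 33 genes. With the difference given as BALB/c minus B6, Ptk2b (2.949, adjusted p = 6.67e-07) and Tafa2 (-1.602, adjusted p = 0.0315) were saturated on no array of either strain, and Tafa2 was at 1.60 in B6 and 0.00 in BALB/c. Saa2 (3.055, adjusted p = 0.0269), Saa1 (2.881, adjusted p = 0.0184) and Cyp4a14 (2.884, adjusted p = 0.0378) were saturated on all 3 B6 knockout arrays, so that their B6 effects could not be read in full. Selenbp2 (-2.664, adjusted p = 0.00206), Gstp1 (-2.072, adjusted p = 0.0318) and Selenbp1 (-1.723, adjusted p = 0.00772) were saturated on all 6 B6 arrays, where no effect could be read, and Gstp1 also on the 3 BALB/c control arrays. By camera, lists differed as well, the male-biased genes by a median of -0.36 (adjusted p = 0.0124, and 0.658 with an estimated correlation), the female-biased genes by -0.41 (0.0158 and 0.658), the PPARα targets by -0.21 (0.0215 and 0.617) and the macrophage markers by -0.19 (0.0152 and 0.77), though 7 male-biased genes, 4 female-biased genes and 7 PPARα targets were saturated on all 6 B6 arrays. Of 100 drawn splits of these arrays, 1, the real split, gave 33 genes and the highest of the others 14. The splits exchanged arrays between sets b and c, whose spread differed (median SD between replicates 0.162 and 0.148 against 0.11 and 0.085). They thus cannot exclude chance for the count or for any 1 gene, and strain and array set cannot be told apart.

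Interferon response genes were higher in the STAT5b knockouts of both strains, with 24 and 18 of 35 past the threshold (28 and 25 adjusted over the list alone), a median of 0.84 in B6 and 0.94 in BALB/c, and adjusted p = 0.0693 and 0.0152 with an estimated correlation. Differences between slides are excluded as the whole cause, since the median was 0.588 or more within every slide that held both genotypes. In BALB/c the macrophage median was 0.264 of the interferon median (0.25, with a bootstrap interval of 0.145 to 0.324, against a bound of 0.469 set for more macrophages). In B6 it was 0.412 of it (0.35, interval 0.316 to 0.56, against a bound of 0.421). Within the 2 BALB/c slides the macrophage medians were 0.29 and 0.131, against interferon medians of 0.588 and 1.026. The bootstrap drew genes, not mice, and the bound was set after the values were seen. More macrophages thus cannot be excluded in either strain, though the BALB/c interval lay under its bound. GH acting through another route where STAT5b is missing cannot be told apart from other explanations: the list was shifted less in little, which lacks GH, than in the B6 knockouts, by a median of -0.775 (camera adjusted p = 2.34e-11, and adjusted p = 0.597 with an estimated correlation), but this was known from the medians beforehand and those groups lie in different array sets, whose B6 controls differed over this list too (median -0.284 in WTb). The interferon pattern is thus a hypothesis, with a change in macrophages still open in both strains.

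Of the 7 major urinary protein genes, 7 fell in little and 4 in the BALB/c knockouts (7 and 7 adjusted over the list alone), but none had a call in the B6 knockouts. Saturated Mup spots could account for this except for Mup9, since 6 of the 7 probes were saturated in Cy3 on all 3 B6 control arrays of that set. A different STAT5b effect in the 2 strains cannot be tested on saturated spots: the median difference of -2.3 cannot be read, and the smallest adjusted p over the 7 genes was 0.122. Mup9, saturated on no array, was at -0.78 in B6 (adjusted p = 0.344) and -2.07 in BALB/c, a difference that did not pass (-1.292, SE 0.723, adjusted p = 0.685). Its BALB/c call was itself lost without at least 1 of the arrays and in at least 1 other setting. A high spread between arrays cannot be told apart either, because saturation also narrows the spread (the median SD of 0.179 was at percentile 52.5 of all tested genes).

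Genes close to Stat5b might change because of donor-strain DNA that came with the knockout allele. Within 10 Mb, 33 of 352 tested genes (9.38%) changed in B6 against 12.3% elsewhere (odds ratio 0.736, 95% interval 0.497 to 1.06, Fisher's exact p = 0.101, adjusted p = 0.404), and 6 of 352 (1.7%) in BALB/c against 2.54% elsewhere (odds ratio 0.664, 95% interval 0.241 to 1.47, Fisher's exact p = 0.393, adjusted p = 0.524). The shares were below those elsewhere in both strains, as written down beforehand for the case without such DNA, but the intervals reach to 1.47, so that it stays open for a few genes.

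For 3 arrays against 3, the 10 possible splits are too few for a share under 0.05: the real split gave 2188 genes in little (highest other split 1), 447 in Tfm (0), 2207 in the B6 knockouts (201), 455 in the BALB/c knockouts (5), 606 between little and Tfm (6) and 3359 between the 2 groups of B6 controls (0). Chance can be excluded for the effect over both strains (2414, highest other of 100 drawn splits 1243), where the splits kept each array in its set. The difference between little and the B6 knockouts gave 881 genes (highest other of 100 drawn splits 322). BALB/c against B6 controls taken as 1 group gave 6179 (highest other of 84 splits 5412). The splits of these 2 comparisons exchanged arrays between sets that were not alike, so they cannot exclude chance. The split with 5412 genes set the 3 WTb arrays apart and so followed an array set, which points to a structure by set among the controls.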

How the results depend on the processing

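The setting with all 6 B6 controls together, like the others here, was chosen before the data were examined, and no test in this part was chosen after a result was seen. Over the alternatives, 125 of 180 counts stayed within 1.5 times their value and 55 moved; 1897 of 2040 list results kept their side of the threshold, 84 lost and 59 gained a call (the medians of 8 B6 knockout lists turned below 0 with median centring); 4531 of 5235 named-gene results were kept, 674 lost and 26 gained a call and 4 changed direction. The cause was not tested unless stated.

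With Agilent's processed signals, counts were 1016 for the BALB/c knockouts, 382 for little against Tfm, 314 for little against the B6 knockouts and 2100 for WTb against WTa, and the B6 and BALB/c effects correlated at r = 0.605; with the deposited series table they were 1013, 382, 318 and 2108, and r = 0.604. With median centring, counts were 347 for little, 53 for Tfm, 447 and 89 for the B6 and BALB/c knockouts, 190 for little against Tfm, 7 for the strain difference of the knockout effect, 2 for little against the B6 knockouts, 385 over both strains, 4 for WTb against WTa and 4304 for BALB/c against B6 controls. Under it Stat5b in BALB/c was at -1.49 (adjusted p = 0.191), Pcx and Fabp4 in the B6 knockouts turned to -0.261 and -0.24, and r was 0.453 for little with Tfm, -0.0711 for Tfm with the B6 knockouts (0.384 with loess) and 0.469 for B6 with BALB/c. With Cy3 alone, counts were 1169 for Tfm, 816 for the BALB/c knockouts and 6899 for WTb against WTa, Khsrp turned to 0.818 and Ptprb in little to -0.009.

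With the stricter filter, which tested fewer genes, the strain difference had 21 genes. With only the arrays of the compared sets, and so fewer samples, counts were 575 for the B6 knockouts, 10 for the strain difference, 409 for little against the B6 knockouts and 1395 for WTb against WTa. The replicate block gave 51 genes for the strain difference and 1347 for little against the B6 knockouts. Residuals of arrays that share a number correlated at -0.098 to 0.358, against -0.409 to 0.249 for other pairs within a set. The main model leaves out any such tie. The 6 B6 controls together gave 671 for Tfm. With the replicate or slide as a block, WTb against WTa and BALB/c against B6 controls could not be fitted.

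With 1 array left out in turn, and so fewer samples, counts ranged from 1321 to 1957 for little, 205 to 336 for Tfm, 1336 to 2801 for the B6 knockouts, 275 to 491 for the BALB/c knockouts, 353 to 586 for little against Tfm, 9 to 125 for the strain difference, 390 to 1833 for little against the B6 knockouts, 1715 to 2891 over both strains, 1348 to 4764 for WTb against WTa and 5626 to 7438 for BALB/c against B6 controls, and r for little with the B6 knockouts from 0.414 to 0.533. Male-biased medians kept their direction and call, from -1.84 to -1.59 in little, -1.17 to -0.82 in Tfm, -0.99 to -0.87 in B6 and -1.35 to -1.10 in BALB/c, as did female-biased medians, from 1.49 to 1.66, 1.53 to 1.64, 1.26 to 1.47 and 1.04 to 1.31. Signal over background limits what can be read of Ghrhr and Ar, and saturation limits 242 genes in the B6 knockouts.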

Other observations

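The complement genes below were chosen after their values were seen, and no test of an explanation was made for them.

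In the terminal complement pathway, the genes C6, C8a, C8b and C9, whose products assemble into a pore in cell membranes, were lower in all 4 mutant livers. C6 and C8a are also on the male-biased list, so their falls were counted there already. C6 was at -3.66 in little, -2.53 in Tfm, -2.35 in the B6 knockouts and -2.86 in the BALB/c knockouts, and C9 at -2.65, -1.30, -1.02 and -1.14. The chains of C8 encoded by C8a (-3.59, -1.27, -0.74 and -0.75) and C8b (-2.95, -1.04, -1.66 and -1.30) were lower too, and all these values passed the limma test. The remaining chain gene C8g and Hc, which encodes C5, did not pass in any of the 4 comparisons. Over 5 scalings and 4 comparisons, 20 tests per gene, C6 was lower and passed in 20, C8a in 17, C8b in 18 and C9 in 18, against 0 for C8g and 1 for Hc. These tests are not independent, since they share the same arrays and the deposited table holds Agilent's own ratio.

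Among the other genes that changed in all 4 comparisons were Acot3 and Acot4, acyl-CoA thioesterases (Acot3 3.12, 3.81, 3.50 and 2.55 in little, Tfm, B6 and BALB/c knockouts, Acot4 1.66, 2.02, 1.51 and 1.07), Raet1d and Raet1e, which encode ligands of an activating receptor of NK cells (Raet1d 1.52, 2.06, 1.93 and 1.32, Raet1e 1.18, 1.88, 2.12 and 1.28), and Vldlr, a lipoprotein receptor (3.75, 1.89, 2.54 and 1.98). Srd5a1, which activates testosterone, was lower in all 4 (-3.0, -1.15, -1.24 and -1.42), as was Elovl3, a fatty acid elongase (-2.51, -1.90, -1.18 and -1.55). Acot3 is also on the female-biased list and Elovl3 on the male-biased list, so both were counted there already.

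Within 10 Mb of the other mutated genes, 14 of 121 tested genes (11.6%) changed near Ghrhr in little against 12.2% elsewhere (odds ratio 0.941, 95% interval 0.497 to 1.65), and 0 of 88 near Ar in Tfm against 2.5% elsewhere (95% interval of the odds ratio 0 to 1.68), so that a higher share near either gene was not seen.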
